A study of Mus musculus with 4 samples.

How the data were processed

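Total RNA from the dentate gyrus of young male C57BL/6J mice, an inbred laboratory strain, was measured on 4 Affymetrix oligonucleotide arrays. Per the labels, these mice were controls that the experimenter handled and did not treat otherwise. Their RNA was taken 1, 2, 4 or 6 h after other mice of the experiment had their last shock, so each time label refers to an event in animals that are not analysed here. Each time had 1 array. The number of mice behind an array, the time of day and the meaning of the ordinal in the sample titles are not given in the sources used here.

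The deposited values are intensity values on a linear scale, 1 per probe set and array, from 0.2 to 88634.4. The software that made them, its background correction and its detection calls are not given in the sources used here. The trimmed mean of each deposited column, with 2% removed at each end, lay between 500.28 and 500.32 over all probe sets. By a rule fixed before the data were examined, columns whose trimmed means lay within 5% of their mean were taken as already scaled, and the intensity values were used as deposited. Whether the authors centred or limited the values in any other way stays unknown.

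The table held 12488 probe sets, of which 66 were control probe sets and were left out, except for the 5'/3' signal ratios of 5 control transcripts. The floor was the 40th percentile of all remaining values of the 4 arrays, a signal of 124.8. Values below it were set to it, and log2 was taken. A probe set was tested if its mean signal reached the floor, which 7480 of 12422 did. Gene symbols came from the platform annotation and were looked up by gene identifier in a RefSeq table of GRCm38.p6. Exactly 1 symbol was given for 10833 probe sets, several for 396 and none for 1193, and 10817 were found by identifier with 0 symbols changed. No gene was named from a probe set with several symbols. The probe set with the highest mean signal stood for its gene, which gave 5691 genes. Where other probe sets of a named gene differ in sign, their values are given, as are some that differ in size. Probe sets marked by the manufacturer as shared within a gene family are uncertain, which among the named genes holds for Ptgds, Itgb1, Sema4b, H2-K2, Snrp1c-ps2, Cryab, Atf3, Nfil3, Penk and Eif2s3y. Other marks in the probe set names, as for Thyn1, Kif5a and Rps13, were not weighed. A gene not called uncertain here is therefore not shown to be measured specifically. No position is given, because the values carry no coordinates and no build.

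With 1 array per time there is no spread between replicates, and the number of arrays limits the precision. Probe sets at least 2-fold apart were counted between 2 h and 1 h, 4 h and 1 h, and 6 h and 1 h, with no test. Differences with 1 side below the floor were counted apart, as bounds. All comparisons against 1 h share that array, so its chance values enter each of them. Of the tests among arrays the design allows, limma's linear trend of log2 signal on hours was used, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment over the probe sets tested. The share of probe sets whose values rose or fell in the order of time was set against the same share under 12 distinct orders of the arrays.

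Before the data were examined, 21 gene lists were fixed, and 20 of them had at least 3 measured members. They covered immediate early, glucocorticoid-responsive, clock, chaperone, ribosomal protein, oxidative phosphorylation, glutamate receptor, GABA and presynaptic genes, markers of neuron and other cell types, of neighbouring tissue, and a sex check. The median log2 difference of a list was placed among 10000 random lists of its size, matched on mean signal in 20 bins. The percentile describes these arrays and is no p-value. Named genes followed a rule fixed at the same time. It took the 12 highest and 12 lowest differences between 6 h and 1 h among genes above the floor on all 4 arrays and ordered in time, and the 6 highest and 6 lowest for 2 h and for 4 h against 1 h. It added the 5 genes with the smallest trend p, up to 4 members of each list with the widest difference between 6 h and 1 h, and a set of textbook genes. Other genes were chosen after their values were seen, and are named as such where they appear.

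On simulated data with the spread of these arrays, the trend test at an adjusted p under 0.05 found 1.49% of 67 probe sets made to differ by a log2 of 1 between 6 h and 1 h, 40.3% of 67 at a log2 of 2 and 86.4% of 66 at a log2 of 3. It called 0.0824% of 7280 unchanged probe sets. Of 2000 simulated lists of 20 probe sets for 6 h against 1 h, 4.85% with no shift lay outside the central 95% of random lists, 26.4% with a shift of 0.2 and 80.3% with a shift of 0.4. The lists were drawn at random from the probe sets tested, so the value with no shift follows from the draw. Lists whose members vary together were not simulated.

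Alternatives were quantile normalization, trimmed mean scaling, floors at the 20th and 60th percentile, the floor as a pseudocount, no filter on low values, size rules of 1.5-fold and 3-fold, the mean of all probe sets of a gene, other codings of time, each array left out of the trend, and a variance trend in limma. Setting 6 h against 2 h was added after seeing the data. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.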

Results

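Gene expression in the dentate gyrus, the part of the hippocampus that holds the granule neurons, was measured in handled control mice at 4 times, with 1 array at 1, 2, 4 and 6 h. The labels give these mice as the controls of a shock experiment. The comparisons here ask how far control tissue taken at different times differed. No array was repeated, so no difference between arrays has a replicate check, and each fold is given without an error.

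The median signal was 171.4 on the 1 h array, 194.6 at 2 h, 200 at 4 h and 215.8 at 6 h, and 56.6%, 59.5%, 60.8% and 63.1% of probe sets lay above the floor. The 90th percentile ran the other way, at 1526, 1490, 1468 and 1455. Over probe sets measured on both arrays, the standard deviation of the log2 difference from the 1 h array was 0.547 at 2 h, 0.456 at 4 h and 0.528 at 6 h, with Pearson's r across probe sets, which are not independent replicates, of 0.935, 0.955 and 0.941. It was 0.496 between 4 h and 6 h, so pairs further apart in time did not differ more throughout. Among probe sets with a mean signal of 139 to 394, the median standard deviation over the 6 pairs of arrays was 0.562, and 8.43% differed at least 2-fold. Among those from 897 up, the values were 0.437 and 2.97%.

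The 5'/3' signal ratio of control transcripts, a measure of how complete the labelled RNA was, also differed. For Gapdh it was 0.255 at 1 h, 0.921 at 2 h, 0.221 at 4 h and 0.681 at 6 h. Pyruvate carboxylase had 0.102, 0.314, 0.192 and 0.340, and beta-actin 0.515, 0.626, 0.411 and 0.315. The 5' signal of pyruvate carboxylase lay below the floor at 1 h and 4 h, at 40.2 and 88.9.

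Between 1 h and 6 h, the longest interval, Ptgds, which encodes the lipocalin-type prostaglandin D synthase, had a signal of 18056 at 1 h, 10987 at 2 h, 8401 at 4 h and 5956 at 6 h, a log2 difference of -1.60. Its probe set is shared within a gene family and so uncertain, and the other probe sets of Ptgds gave -0.96 and -1.30. Bola2 was lower at 6 h by a similar amount, with 1119 at 1 h and 350.3 at 6 h (log2 -1.68). In the other direction, Snhg11, a host transcript of small nucleolar RNAs, went from 132.5 to 609.0 (log2 2.20), Thyn1 from 166.3 to 696.9 (log2 2.07) and Tcf25 from 155.9 to 587.5 (log2 1.91). None of these genes passed the trend test over all genes.

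Of the 4803 genes above the floor on all 4 arrays, 475 had values ordered in time, and the 24 named here are the ends of that set. Among the lower ones at 6 h, Ahnak, a large scaffold protein, differed by a log2 of -1.51, and Cryz, a quinone reductase, by -1.32. Txndc5, a disulfide isomerase of the endoplasmic reticulum, had -1.31 and Man1b1, a mannosidase of the secretory pathway, -1.20. Arf4, a small GTPase of the Golgi, went from 1688 to 722.3 (log2 -1.23). Pam16, a subunit of the mitochondrial protein import motor, had 1104 at 1 h and 471.7 at 6 h (log2 -1.23). Med28, a Mediator subunit, had 1499 and 661.6 (log2 -1.18). Prp2 had -1.31, and its other probe set, below the floor at 6 h, -1.97 or lower. For Pcp2 and for Itgb1, the common beta chain of many integrins, both at -1.21, another probe set gave the opposite sign, at least 0.40 for Pcp2, where 1 h lay below the floor, and 0.22 for Itgb1, and the Itgb1 probe set is uncertain.

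The 12 genes higher at 6 h had 1 h signals of 125.0 to 203.2, near the floor of 124.8. Mllt10 (log2 1.73) had a signal of 125.0 at 1 h, and Esyt3, an extended synaptotagmin (log2 1.44), had 127.9. Hnrnpu, a nuclear RNA-binding protein, had a log2 of 1.48, Nxf1, the mRNA export receptor, 1.39, and Ints7, an Integrator subunit, 1.51. Invs, a protein of the primary cilium, had a log2 of 1.55, Man2a1, a Golgi mannosidase, 1.48, Strn4 1.39 and Fcgbp 1.38. Other probe sets gave 0.93 for Tcf25, 0.67 for Fcgbp and -0.07 for Thyn1.

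**Figure D1:**
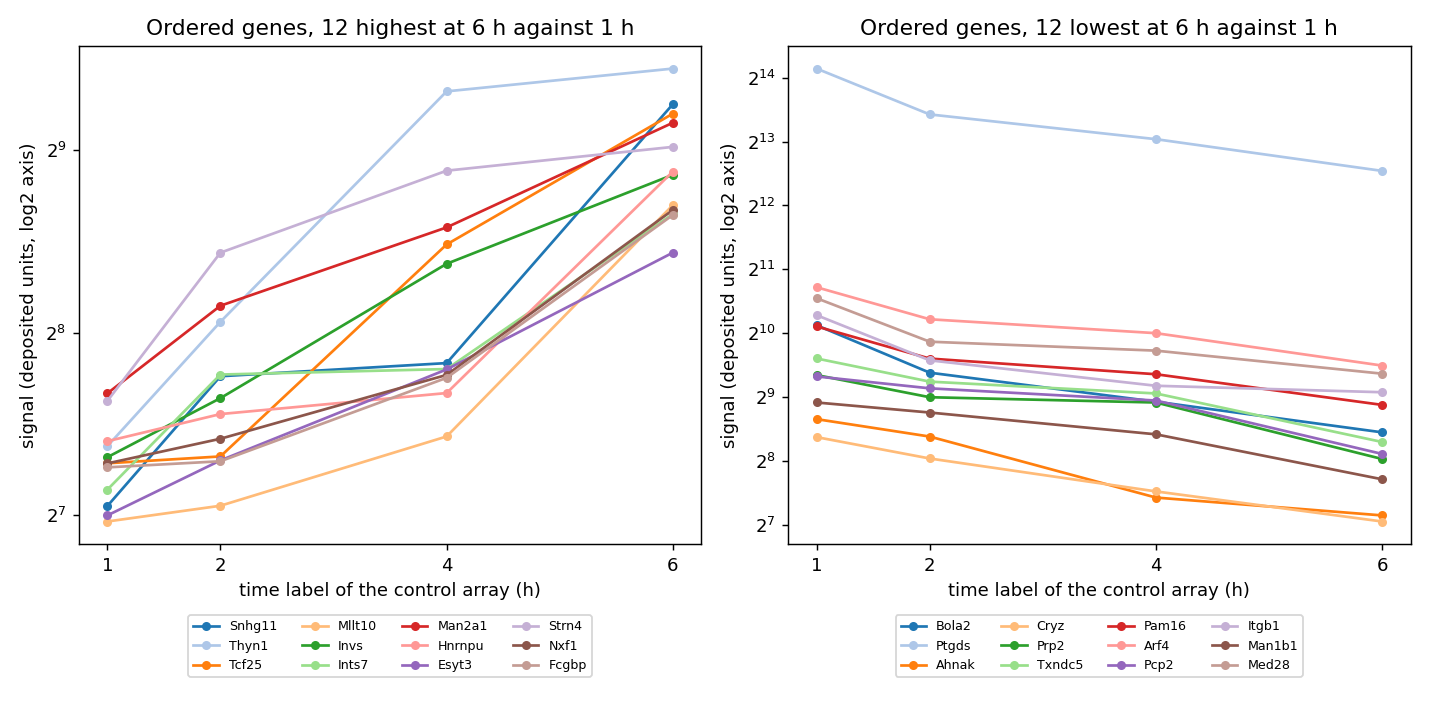
Signal in deposited units on a log2 axis against the time label of the array in h, 1 line per gene and 1 point per array, for the 12 highest and 12 lowest ordered differences between 6 h and 1 h. Snhg11 ends at 609.0 from 132.5, and Ptgds at 5956 from 18056, with no replicate at any time.

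Over probe sets measured on both arrays, 273 were at least 2-fold higher at 6 h than at 1 h and 144 lower, and a further 170 and 80 had 1 side below the floor. Under quantile normalization the split was 167 higher and 166 lower, so the share higher moved from 65.5% to 50.2%. With the floor at the 60th percentile, 53 were higher and 71 lower, and with the floor as a pseudocount 58 and 60, so the direction turned.

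Genes of mitochondrial oxidative phosphorylation were lower at 6 h than at 1 h in 36 of 42 measured members, 2 of them by at least 2-fold. Their median log2 difference was -0.42, at percentile 0 of the matched random lists. Ndufv2, a complex I subunit, had 3537 at 1 h and 1697 at 6 h (log2 -1.06), although another probe set of Ndufv2 gave 0.13. The ATP synthase subunits Atp5e (log2 -1.03) and Atp5o (log2 -0.94) and the succinate dehydrogenase subunit Sdhb (log2 -0.87) were also lower. The list was lower, too, at 2 h and 6 h than at 1 h and 4 h (median -0.20, percentile 0.95, 31 of 42 members). The Gapdh 5'/3' ratio differs along the same line, with 0.681 at 6 h against 0.255 at 1 h, but that of beta-actin does not, with 0.315 against 0.515. Ribosomal protein genes were lower in 14 of 20 members, with a median of -0.24 at percentile 5.85, inside the central 95%. Rps3 had 10082 at 1 h and 5565 at 6 h, Rpl8 11759 and 6712, and Rps4x 11189 and 6810, while Rps13 had 270.6 and 672.9.

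Glutamate receptor and postsynaptic genes were higher at 6 h in 15 of 18 members, 5 of them at least 2-fold, with a median of 0.41 at percentile 99.9. Gria3, an AMPA receptor subunit, went from 144.7 to 551.4 (log2 1.93), and Grik5, a kainate receptor subunit, from 519.6 to 1249 (log2 1.26), although the other probe set of Grik5, below the floor at 6 h, gave -0.95 or lower. Set against the 2 h array, chosen after seeing the data, the median of this list turned to -0.14. Grin2b and Grin2d, subunits of NMDA receptors, had 303.0 and 296.0 at 6 h and lay below the floor at 1 h. Presynaptic vesicle genes had a median of 0.16 at percentile 96.7, with Syt11 at a log2 of 1.60 and Syt1 at 0.82, both synaptotagmins, Nsf at 0.68 and the vesicle GTPase Rab3a at -2.10. The Gapdh 5'/3' ratio was higher at 6 h than at 1 h, at 0.681 against 0.255, while that of beta-actin was lower, at 0.315 against 0.515.

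Choroid plexus and ependyma markers were lower at 6 h in 6 of 8 members (median -0.37, percentile 1.58). Ttr, the transthyretin of choroid plexus, had 864.2 at 1 h and 307.0 at 6 h, Foxj1, a regulator of motile cilia, 357.9 and 131.7, and the growth factor gene Igf2 2836 and 1449, while Folr1, a folate receptor, had 127.8 and 316.0. Set against the 2 h array, a setting chosen after seeing the data, the median turned to 0.61. Markers of meninges and fibroblasts, a list that also holds Igf2 and Ptgds, were lower in 8 of 13 members (median -0.44, percentile 0.195). Among them Pcolce had a log2 of -1.37 and Mgp -1.05.

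The remaining lists lay inside the central 95% at 6 h. Immediate early genes, which neurons switch on with activity, had a median of 0.15 over 26 members, 18 higher and 7 lower. Fos had a signal of 208.4 at 1 h and 220.2 at 6 h, Egr1 995.2 and 971.2, Junb 314.7 and 392.8, and Nr4a1 380.2 and 400.6. As examples, Btg2 had a log2 of 0.78, and Fosl2, Atf3 and Crem had 419.8, 291.8 and 194.3 at 6 h from below the floor. Glucocorticoid-responsive genes had a median of 0.01 over 20 members, with Fkbp5 at 1175 and 1164 and Sgk1 at 915.7 and 858.3. Gjb6, a connexin (log2 -1.49), Ddit4 (log2 -1.17) and the metallothionein Mt1 (log2 -0.98) were lower, and another probe set of Gjb6 gave -0.27. Pdk4 had 239.8 at 6 h from below the floor. Clock genes had a median of 0.19 over 16 members, with Nr1d1 at a log2 of -0.98, Rora at 0.97 and Cry2 at 0.72, and Nfil3 at 290.4 from below the floor. Per2 had 133.5 at 6 h from below the floor. Chaperone genes had a median of -0.02 over 18 members, with Cryab at -1.21 on an uncertain probe set, Hspd1 at -0.80, Hspe1 at -0.75 and Hsp90aa1 at -0.69.

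Among the neuron markers, dentate granule genes had a median of 0.00 over 12 members at 6 h, with Calb1, the calbindin of granule cells, at 2285 at 1 h and 1808 at 6 h. Prox1, the granule cell transcription factor, had 155.8 and 147.8, Rasgrp1 a log2 of 1.04, Tiam1 -0.94, Npy1r 0.86 and Tdo2 -0.93, with 0.53 on another probe set of Tdo2. A further probe set of Tiam1 gave -0.35. GABA and interneuron genes had -0.02 over 16, with Gad1, a GABA-synthesising enzyme, at 4322 and 4536, Sst at 4242 and 3680, Npy at 2117 and 1443, Penk at -0.71, Cck at -0.56 and Gabra2 at 0.56. Markers of newborn neurons and progenitors had 0.24 over 17 (percentile 91.4), with Igfbpl1 at 1.03, Mki67 at 0.89, Sox11 at 0.79 and Nes at -0.66. CA and hilar markers had -0.23 over 14 (percentile 5.88), with Spock1 at -0.66, Wfs1 at -0.60, Nnat at 0.57 and Calb2 at 0.48.

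Of the other cell types, astrocyte markers had a median of -0.17 over 16 at 6 h, with Gfap at 2455 at 1 h and 2031 at 6 h (another probe set of Gfap gave 0.41), Ntsr2 at a log2 of -0.74, Slc1a2 at 0.75 and Atp1b2 at 0.68. Myelin markers had -0.16 over 10, with Mbp at 4303 and 4128, Qk at -0.63, Mog at -0.52, Mobp at -0.45 and Mal at 0.52. All 3 other probe sets of Mobp gave the opposite sign, 0.61, 0.27 and 0.45. Microglia markers had -0.15 over 10, with Tyrobp at -1.13, Ctss at -0.83, C1qb at -0.35 and Cx3cr1 at 0.81. Vascular markers had 0.05 over 13, with Myl9 at -1.07. Slc2a1 and Pecam1 had 315.1 and 222.8 at 1 h and lay below the floor at 6 h, and Kdr had 231.7 at 6 h from below the floor. Red blood cell markers had -0.32 over 4, with Hba-a1 at 3458 and 2564, Bpgm at -0.42, and Hbb-b2 at -0.21, while Slc4a1 had 181.6 from below the floor. Markers of thalamus, hypothalamus and cortex had 0.34 over 14 (percentile 85.9), with Zic2 at 0.99, Zic1 at 357.7 at 1 h and below the floor at 6 h, and Pomc at 273.0 from below the floor. Of the sex check list, Eif2s3y had 156.0, 139.8, 208.6 and 191.3 over the 4 times.

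At 2 h, 16 of 18 glutamate receptor and postsynaptic genes and 11 of 16 presynaptic genes were higher than at 1 h. Among single genes, Nsmf, a synapse to nucleus messenger, had 357.4 at 1 h and 2647 at 2 h (log2 2.89), Kif5a, a neuronal kinesin, 253.6 and 1520 (log2 2.58), and Atp6v0a1, a subunit of the vesicular proton pump, 335.4 and 1664 (log2 2.31). Pdia6 (log2 2.80), Pla2g4f (log2 2.46) and Rnd2 (log2 2.32) completed the highest 6. The lowest were Gtf2f2 (log2 -2.60), Ttr with 864.2 and 179.8 (log2 -2.27), Sema4b (log2 -1.99, on an uncertain probe set), Smyd2 (log2 -1.91), Trnt1 (log2 -1.91) and Plec, the cytoskeletal linker plectin (log2 -1.89). Other probe sets gave -0.34 for Nsmf, -0.04 for Sema4b, and, with 1 side below the floor, -0.58 or lower for Smyd2 and at least 0.21 for Sema4b, and -0.18 and 1.47 for Pdia6.

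The glutamate receptor list had a median of 0.64 at percentile 100 at 2 h, and the presynaptic list 0.50 at percentile 100. Syt11 had 583.3 at 1 h and 2849 at 2 h, and Syt1 850.1 and 2412. The Gapdh 5'/3' ratio was 0.921 at 2 h against 0.255 at 1 h. Microglia markers (median 0.40, percentile 98.5) and markers of neighbouring brain regions (0.46, percentile 99.1) were also above the random lists. Choroid plexus markers (-0.54, percentile 0.43) and oxidative phosphorylation genes (-0.27, percentile 1.99, 33 of 42 members lower) were below. Chaperone genes had 0.22 at percentile 97.4. Per1, a clock gene that is also induced by activity, had 159.9 and 514.2, and Dbp, a clock output factor, 559.0 and 205.5. In all, 313 probe sets were at least 2-fold higher and 114 lower at 2 h, with a further 132 and 32 as bounds.

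At 4 h, Thyn1 (log2 1.94), Nppa, the atrial natriuretic peptide (log2 1.94), Pdia3, a disulfide isomerase (log2 1.69), Eef1b2, a translation elongation factor (log2 1.65), Cdc25a, a cell cycle phosphatase (log2 1.65), and Abcb10 (log2 1.61) were the highest against 1 h. Their 1 h signals were 135.2 to 166.3, near the floor of 124.8, and another probe set of Thyn1 gave 0.07. Nexmif (log2 -2.21), Ttr (log2 -2.17), H2-K2 (log2 -1.81), Asb6 (log2 -1.70), Snrp1c-ps2 (log2 -1.68) and Hars, the histidyl-tRNA synthetase (log2 -1.59), were the lowest, with H2-K2 and Snrp1c-ps2 on uncertain probe sets. Ribosomal protein genes had a median of -0.31 at percentile 0.03, with 15 of 20 members lower, and oxidative phosphorylation genes -0.23 at percentile 0.14, with 32 of 42 lower. Newborn neuron and progenitor markers were higher in 16 of 17 members (median 0.28, percentile 97.7). Glutamate receptor genes (0.06, percentile 65.3) and presynaptic genes (0.02, percentile 60.2) lay inside the central 95%, and the Gapdh ratio was 0.221. At least 2-fold higher were 149 probe sets and lower 80, with 108 and 53 as bounds. Under quantile normalization they were 110 and 98, so the share higher moved from 65.1% to 52.9%. With the floor at the 60th percentile, 24 were higher and 28 lower, and with the floor as a pseudocount 23 and 34, so the direction turned.

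**Figure D2:**
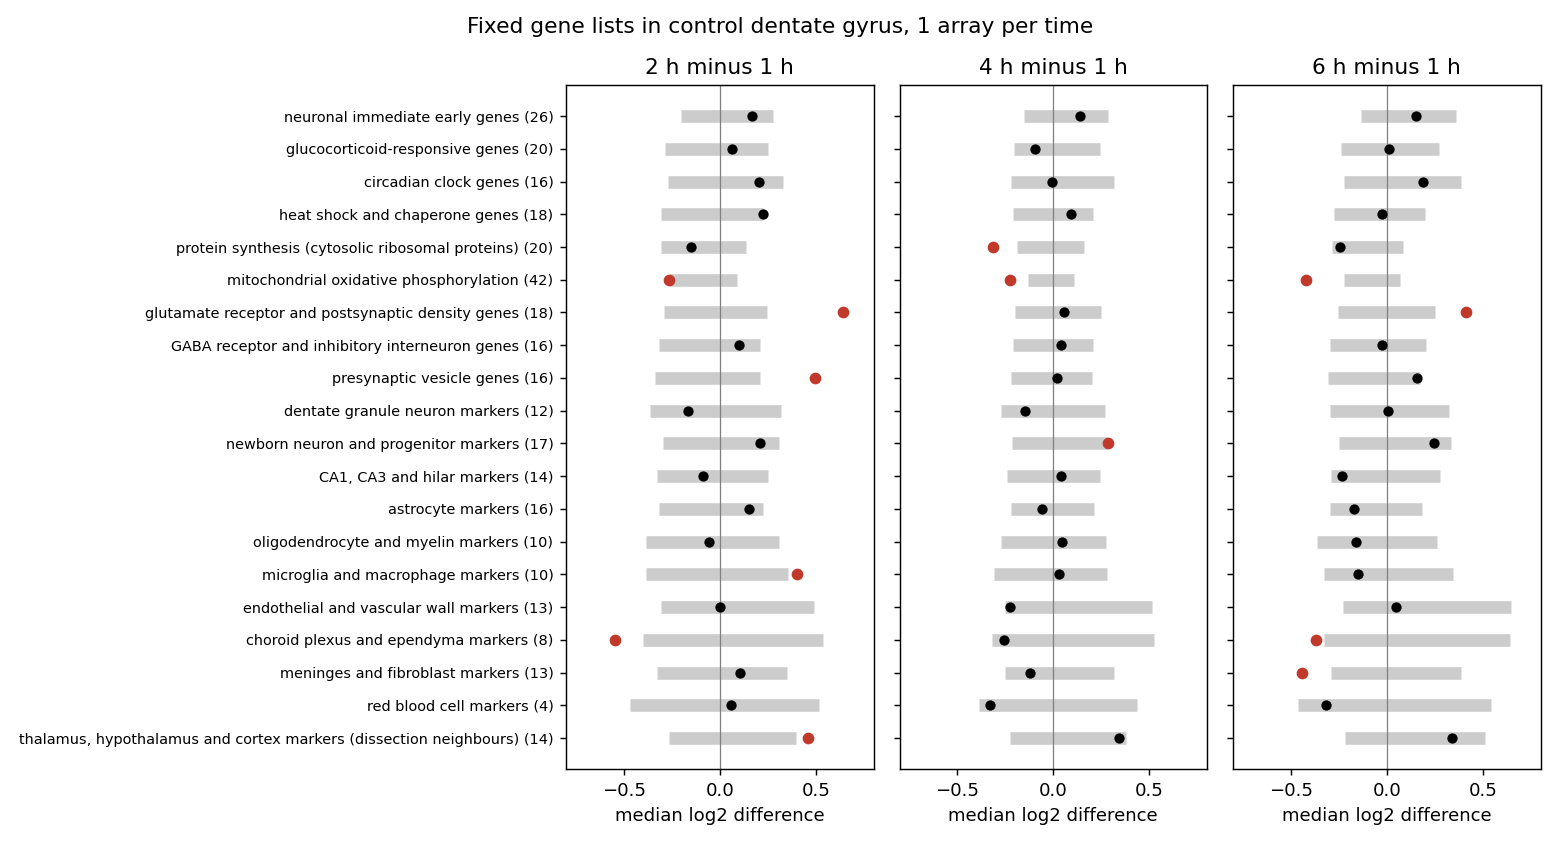
Median log2 difference of each fixed gene list from the 1 h array at 2, 4 and 6 h, with the number of measured members in brackets. Grey bars span the central 95% of 10000 random lists matched on signal, and red points lie outside them, as oxidative phosphorylation genes do at each time (-0.27, -0.23 and -0.42).

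Over the 3 comparisons, 6, 3 and 4 of 20 lists at 2, 4 and 6 h lay outside the central 95%. By chance 1 each would, if the members of a list varied independently. The 3 share the 1 h array, so part of any likeness between them comes from that array.

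In limma's linear trend with time, 0 of 7480 probe sets had an adjusted p under 0.05 (smallest adjusted p 0.721). At an unadjusted p under 0.05 there were 509, 324 with a slope above 0 and 185 below, where 374 would by chance. Adjusted over the list alone, 0 members of any list passed (smallest limma adjusted p 0.0504). The smallest p belonged to Tcf25, with a slope of 0.415 log2 per h (SE 0.0786), then Abcf2 (-0.449), Rnh1, the ribonuclease inhibitor (-0.368), Gpaa1 (-0.486, with 6 h below the floor) and Thyn1 (0.426), each with a limma adjusted p of 0.721. Another probe set of Gpaa1 had the opposite sign between 6 h and 1 h, at 0.20. For Rnh1 another probe set gave only -0.15 between these arrays, against -1.71 on the one used. Of 6119 probe sets above the floor on all 4 arrays, 613 or 10.02% were ordered in time, 328 upward and 285 downward. Values with no structure give 8.33%, and the order 1, 4, 6, 2 h gave 10.3%, so the real order ranked 2 of 12.

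**Figure D3:**
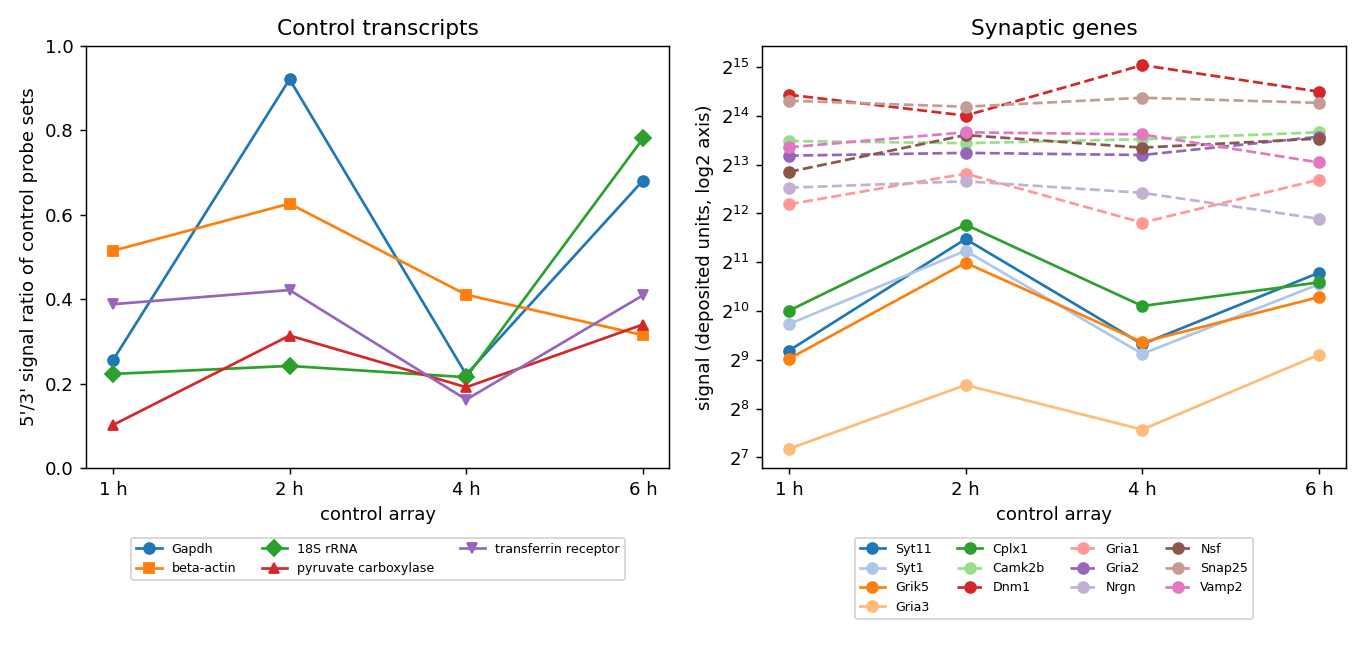
Left, the 5'/3' signal ratio of 5 control transcripts on each array, with Gapdh at 0.255, 0.921, 0.221 and 0.681. Right, signal of 13 synaptic genes in deposited units on a log2 axis, with dashed lines for the 8 with a mean signal of at least 5000. Solid lines are the 5 others above the floor on all arrays with the highest contrast of 2 h and 6 h over 1 h and 4 h, and both rules were chosen after the values were seen. Syt11 and Syt1 are higher at 2 and 6 h, while Dnm1 is highest at 4 h.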

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

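Of the tests in this part, only quantile normalization of the synaptic lists and the orders counted for the trend were chosen before their results were seen. The test of other probe sets and that of other neuron genes replaced earlier forms, which had left out probe sets that moved themselves or had used a few abundant synaptic genes.

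Arrays that stood far from the other 3 appeared in 3 of 28 sets of values, where chance gives about 1.4. The 5'/3' ratio of 18S rRNA was 0.781 at 6 h against 0.215 to 0.242 on the other arrays (gap over range 0.953). The ratio of transferrin receptor was 0.162 at 4 h against 0.388 to 0.422 (gap over range 0.871). It rests on a 5' signal below the floor on every array, at 24.8 at 4 h and up to 78.9 on the others. Markers of thalamus, hypothalamus and cortex lay lowest at 1 h, with a median deviation of -0.34 (gap over range 0.82902, just above the limit used).

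Most members of the synaptic lists were higher at 2 h and 6 h than at 1 h and 4 h (15 of 18 glutamate receptor and postsynaptic genes and 10 of 16 presynaptic genes), with a median contrast of 0.36 over 34 members but -0.03 over the 8 brightest, 4 of them higher and 4 lower. Quantile normalization kept the contrast, at 1.05 of its value, which argues against unequal signal distributions. Differences in the length of labelled RNA are a candidate explanation. The 5'/3' ratio was higher on both the 2 h and 6 h arrays for 4 of 5 control transcripts, and not for beta-actin. It was higher by little for transferrin receptor, and for 18S rRNA at 2 h (0.242 against 0.223 at 1 h). The 5' signal of transferrin receptor lay below the floor on every array (24.8 to 78.9). That of pyruvate carboxylase did so at 1 h and 4 h (40.2 and 88.9), so both ratios rest on low signals. Of the genes with a probe set at least 2-fold higher on that pair of arrays, other probe sets of the same gene kept 0.0755 of the contrast (95% bootstrap interval -0.0481 to 0.305, 35 pairs in 28 genes), as RNA length would give, and as noise in single probe sets would too. Granule and GABA genes had a contrast of -0.0731 with an interval of -0.27 to 0.28 over 28 genes, below the 0.36 of the synaptic lists. No interval was taken for the 0.36, and the interval over genes does not cover differences between single arrays. Whether a larger share of neurons gave the whole contrast, a part of it or none therefore cannot be told apart. A biological difference between the times was not tested.

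Genes of oxidative phosphorylation and, less far, ribosomal proteins were lower at 6 h than at 1 h, and both were lower at 4 h too (medians of -0.23 and -0.31, percentiles 0.14 and 0.03). Compression of bright signals was set against 10000 random lists of matched signal. Of these, 0 had a median as low as the first list at 6 h. For ribosomal proteins it was 3 at 4 h and 585 at 6 h. The first list at 6 h and ribosomal proteins at 4 h were thus lower than nearly all lists of similar mean signal. The same comparison had set them apart, and signals differ within a matching bin, so it does not decide on compression. Compression stays open for both lists. Quantile normalization left 0.681 of the first difference at 6 h and 0.627 of the other, so it removed a part of each, which does not decide on the rest. The median slope of both lists was -0.07 per h in the real order and at most 0.06 in size in any other, so 1 of 12 orders reached it, and 12 orders are too few for a share under 0.05. RNA length was not tested for these lists and stays open, as does time itself. The first list was lower at 2 h and 6 h than at 1 h and 4 h (median -0.20, percentile 0.95, 31 of 42 members). Along this contrast 4 of 5 control ratios also differed, those of pyruvate carboxylase and transferrin receptor on 5' signals partly or wholly below the floor. Ribosomal proteins did not follow the contrast (-0.12, percentile 40.3), and at 4 h the Gapdh ratio was not higher (0.221 against 0.255 at 1 h).

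Ttr and Ptgds were higher at 1 h than the mean of the later arrays, by a log2 of 1.98 and 1.14. Choroid plexus tissue in the 1 h sample is a possible source, but the other 7 measured markers had a median of 0.41 with a 95% bootstrap interval of -0.25 to 0.65, so it cannot be told apart from no carryover. Igf2 and Foxj1 were higher at 1 h by 0.65 and 0.68, while Folr1 and Ace went the other way, with 127.8 and 151.8 at 1 h, near the floor, against 316.0 and 267.6 at 6 h. Meninges as a source cannot be told apart either, since 6 collagen and matrix genes had a median of -0.0297 with an interval of -0.38 to 0.21, and Col1a2, the brightest of them, was lower at 1 h (-0.40). A biological difference between the times was not tested.

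For the linear trend, 3 of 12 orders of the arrays gave at least as many probe sets at an unadjusted p under 0.05, with 509 in the real order and 545 in the highest other, and 12 orders cannot give a share under 0.05.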

How the results depend on the processing

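The arrays of 6 h against 2 h were chosen as an alternative after seeing the data. The other settings were fixed before. Counts of 2-fold differences moved with the settings, and the cause was not tested beyond what a lower or higher limit does by construction. In the order 2 h higher and lower, 4 h higher and lower, 6 h higher and lower against 1 h, they were 739, 357, 650, 323, 965 and 433 with the floor at the 20th percentile, 143, 63, 24, 28, 53 and 71 at the 60th, and 151, 48, 23, 34, 58 and 60 with the floor as a pseudocount. At the 60th percentile and with the pseudocount, lower probe sets outnumbered higher ones at 4 h and 6 h, the reverse of the counts with the floor as used. A 1.5-fold rule gave 943, 665, 667, 508, 996 and 637, and a 3-fold rule 61, 15, 14, 11, 22 and 17. Quantile normalization gave 167 higher at 6 h. Against 2 h in place of 1 h, 231 were lower at 6 h and 215 higher. The standard deviation of the 6 h differences was 0.725 and 0.450 with the floor at the 20th and 60th percentile and 0.411 with the pseudocount. The pseudocount put 5 lists outside the central 95% at 4 h. Against 2 h, 7 lists lay outside at 6 h, 3 of them shared with the 4 outside against 1 h, and the medians of glutamate receptor genes (-0.14) and choroid plexus markers (0.61) changed sign. Among other values, 344 list medians moved by less than the spread of random lists and 34 by more, and 223 values of named genes stayed within the spread between arrays while 41 moved beyond it, with no change of sign. The trend called 0 probe sets under each of 13 alternatives, leaving out each array included (0 to 0), though without the 6 h array the number at an unadjusted p under 0.05 was 219 in place of 509. The trend test found few changes of a log2 of 1 on simulated data (1.49%), so its count of 0 does not show that signals stayed level. Low signals limit the folds, as 8.43% of probe sets in the lowest signal band differed 2-fold between arrays against 2.97% in the highest. No paired analysis was possible because each time has 1 array.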

Other observations

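The genes named in this part, the limit of 5000 and the look at separate pairs of arrays were chosen after the values were seen, and the test of the division by time before. Among genes above the floor on all 4 arrays, the highest contrast of 2 h and 6 h over 1 h and 4 h belonged to Nsmf (7.19-fold, although its other probe set had a log2 contrast of -1.09), Syt11 (3.67-fold), Atp6v0a1 (3.51-fold) and Scn8a, a neuronal sodium channel (3.09-fold). Lin7b, a scaffold of synaptic junctions, had 2.90-fold, Syt1 2.76-fold, Grik5 2.72-fold (log2 -1.30 or lower on its other probe set, below the floor at 2 h and 6 h), Gria3 2.68-fold and Nnat 2.67-fold. Genes outside the synaptic lists ranked between these, with Akap8l at 2.96-fold, Josd2 at 2.88-fold, Trim37 at 2.84-fold and Rnf112 at 2.78-fold. Snx2 had 2.81-fold (log2 0.35 on another probe set) and Atp1b2, of the astrocyte list, 2.70-fold. The 8 members of the synaptic lists with a mean signal of at least 5000 went both ways, 4 higher and 4 lower at 2 h and 6 h, with a median log2 contrast of -0.03. Dnm1, the brightest, had -0.49 and a signal of 22111, 16444, 33666 and 23099 over the 4 times. Vamp2, Nrgn and Snap25 had -0.13, -0.20 and -0.11, Camk2b 0.05, Gria2 0.22, Nsf 0.47 and Gria1 0.76. Other probe sets gave the opposite sign for Vamp2 (at least 1.91, with 1 h below the floor) and the same sign for Dnm1 (-0.41), Gria1 (1.24) and Gria2 (0.16 and 0.77).

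The 2 h and 1 h arrays and the 6 h and 4 h arrays share no array. The contrast was picked after all 4 arrays were seen, however, so the second pair is no independent check. Part of the shares and counts that follow comes from that choice, and they are descriptive only. Among probe sets above the floor on all 4 arrays, a narrower set than in the counts of 2-fold differences, 284 were at least 2-fold higher at 2 h than at 1 h. Of these, 68.3% were higher at 6 h than at 4 h, against 51.2% of all, with a median log2 difference of 0.28. In the same set, 105 were at least 2-fold lower at 2 h, and 39.0% of them were higher at 6 h than at 4 h. Without overlap between the pairs of arrays, 105 probe sets were at least 2-fold higher and 30 lower at 2 h and 6 h. For 4 h and 6 h against 1 h and 2 h the counts were 37 and 22, and for 1 h and 6 h against 2 h and 4 h they were 19 and 22.

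The hypothesis that time of extraction is the main structure shared between arrays was tested by dividing the arrays in pairs and correlating, across probe sets, differences taken from separate arrays. The mean r was -0.0359 for 4 h and 6 h against 1 h and 2 h, 0.115 for 2 h and 6 h against 1 h and 4 h, and -0.0791 for 1 h and 6 h against 2 h and 4 h. These 3 means share the same correlations with opposite signs and sum to 0 by construction, so only their ranking is read. The division by time was therefore not the one these arrays shared most, which rests on 4 arrays and on probe sets that are not independent replicates.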
